A study of Homo sapiens with 30 samples.

How the data were processed

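Gene expression was measured by sequencing of polyA RNA from 30 cultures of macrophages derived from the line 201B7, in 5 groups of 6 that share the same 6 differentiations. The labels describe strand-specific libraries. The deposited values are counts, which the authors made as whole numbers of reads per Ensembl gene ID, without normalization. The submitters' processing notes name STAR 2.5.2b for alignment and featureCounts 1.5.1 for counting. The genome build, the annotation release and the strand setting are not given in the sources used here. The table holds 90 value columns, of which 30 carry the name of a sample of this study and were used. The other 60 could not be matched to a sample and were not used. Of the 58050 gene IDs, 57446 (99%) were given a symbol from a table of gene names or from GENCODE release 29.

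Totals per library were 29.8 to 44.6 M counts, so that counting error is small for genes at 5 CPM or more. Genes with few counts were left out with filterByExpr by group, which kept 17599 genes. Libraries were scaled by TMM (factors 0.935 to 1.033). The counts of all 30 libraries were fitted in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group, estimated dispersions and robust quasi-likelihood, and groups were compared by the quasi-likelihood F test. The median biological coefficient of variation was 12.4%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. The comparisons were each cytokine with medium and TNFalpha with IL1beta, and contrasts between cytokines served to find genes raised selectively. Where a group had no count, the fold is a lower bound from a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its 95% interval from the counts.

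Gene lists came from general knowledge and were chosen, as were the tests, the naming rule and most alternatives, before the data were examined. There were 38 lists, and 829 of their 831 entries matched a gene ID (2 did not). They cover targets of NF-kB, of interferons and of TGF-beta, antigen presentation, chemokines and receptors, metabolism, cell cycle and death, drug targets, markers of other cell types, and transcripts that follow RNA quality. A list with at least 5 tested members was tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and adjusted over 185 tests (37 lists, 5 comparisons). Camera asks whether the members moved more than other genes did. It was repeated with the correlation estimated for each list, which is the stricter test. The rotation test fry gives one p for members that move on balance one way and another, mixed p for change in either direction, and neither compares the list with other genes. Members were also counted with p adjusted over the list alone. The results of 37 of the 38 lists are reported, and 1 list is left out of the text and of the heatmap.

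The genes named are the 10 with the largest rise and the 10 with the largest fall in each comparison with medium (6 and 6 for TNFalpha with IL1beta), the 5 largest among those raised selectively, and up to 4 members of each list. They had to pass the threshold, reach 5 CPM in the higher group, carry a symbol that is not a clone or locus name and move the same way in all 6 differentiations, while list members had only to pass. Genes of the ligands and their receptors were always eligible. From these, the text gives a selection. The 3 genes raised selectively by TNFalpha were named after their values were seen, since the count was small.

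The alternatives were DESeq2-type size factors, no filter, a filter of 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the differentiation number as a replicate block in edgeR and in DESeq2, a change of at least 2-fold, an adjusted p under 0.01, and leaving out each differentiation. Leaving out the medium library of differentiation 5, or the IFNgamma library of differentiation 6, was chosen after seeing the data. That the numbers pair libraries of different groups was checked on values with the group means removed. Libraries with the same number had a median r of 0.22 (60 pairs, 0.02 to 0.48) and those with different numbers -0.06 (300 pairs, -0.3 to 0.44), and 29 of the 30 libraries correlated best with libraries of their own number. The main fit does not use this pairing. For TNFalpha against medium it called 466 genes, where the replicate block in edgeR called 1282. Genes and lists given as not passing with TNFalpha may therefore pass with the block. No library is a copy of another of its group: over the 75 pairs within groups the chi-square per degree of freedom was 7.24 to 87.7. The IFNgamma library of differentiation 6 stood apart, with 51.4 to 87.7 in its pairs and 8.2 to 31.6 in the other IFNgamma pairs. Pairs with the TGFbeta1 library of differentiation 2 had 34.8 to 59.9, and the other TGFbeta1 pairs 9.82 to 27.5.

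The model was tested on simulated data with changes planted in 50 genes of each size. It found 48% of genes changed 1.25-fold, 76% at 1.5-fold, 94% at 2-fold and 98% at 4-fold, with 9 false calls among 167 and none in a comparison without change. The simulated libraries were drawn without differences between differentiations, and the replicate block in edgeR gave 167 calls too. These rates therefore do not cover the pairing of the real libraries. Of 200 random lists, camera of limma gave 1 a p under 0.05, and the list with planted changes was found. Genes were simulated independently, so this could not check camera on lists whose members move together. In the real lists the estimated correlation reached 0.953. Sums of squares per gene gave the shares of variance by group and by differentiation. For the agreement between cytokines, unchanged groups were simulated 20 times against the same medium libraries, and the differentiations were split 20 times into 3 and 3 so that 2 cytokines used different medium libraries.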

Results

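RNA from 30 cultures of macrophages derived from the established human induced pluripotent stem cell line 201B7 was sequenced. Cells of 6 independent differentiations, numbered 2 to 7, were each kept in medium or exposed to TNFalpha at 5 ng/mL, IL1beta at 5 ng/mL, IFNgamma at 0.4 ng/mL or TGFbeta1 at 2 ng/mL, which gives 5 groups of 6 libraries. The time of exposure is not given in the sources used here. Libraries held 29.8 to 44.6 M counts assigned to genes (M, mega). The mean total was 34.5 M ± 3.67 (SD, n = 6) in medium, 35.8 ± 3.18 with TNFalpha, 35.5 ± 2.81 with IL1beta, 36.3 ± 5.04 with IFNgamma and 34.8 ± 4.73 with TGFbeta1. Mitochondrial transcripts took 6.99% ± 0.71 of the counts in medium, 6.15% ± 0.78 with TNFalpha, 6.12% ± 0.58 with IL1beta, 6.08% ± 0.52 with IFNgamma and 6.91% ± 1.3 with TGFbeta1 (SD, n = 6). After genes with few counts were left out, 17599 genes were tested. In what follows, ± after a log2 fold change is its standard error, levels are mean CPM values ± SD, and each group has n = 6 libraries. A gene named as rising or falling moved the same way in 6 of 6 differentiations unless another number is given. Counts of genes take every gene that passed the test, however its single differentiations moved.

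The study set out to compare the signalling that these cytokines induce in the macrophages. Libraries grouped by cytokine first. The median gene had 49.5% of its variance between cytokine groups, 15.9% between differentiations and 27.5% left over. With only the genes called in any comparison with medium, the cytokine share was 67.4% and that of the differentiation 11.8%. These genes were chosen for differing between groups, so a larger cytokine share is built in. The first principal component held 32.5% of the variance, of which 99.6% lay between groups, and the second held 21.3%, of which 98.6% lay between groups. The fourth component, with 5.2% of the variance, lay mostly between differentiations (75.6%).

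**Figure D1:**
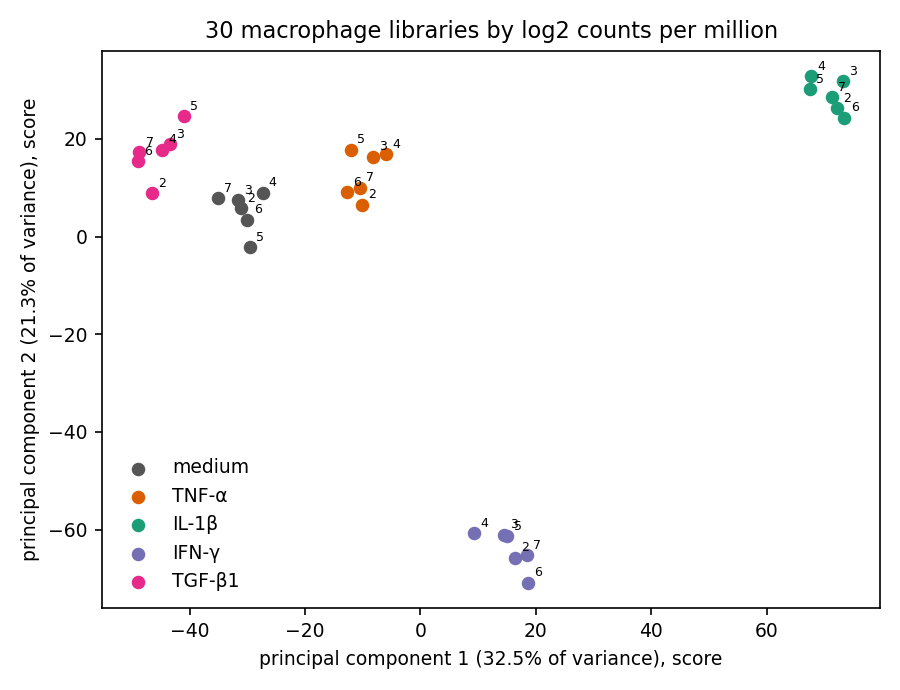
Each point is 1 of the 30 libraries on the first 2 principal components of log2 CPM (the axes, in component units), coloured by group and labelled with its differentiation number. On the first component the IL1beta libraries lie between 67.5 and 73.5 and the TGFbeta1 libraries between -49 and -41, while the IFNgamma libraries lie between -70.8 and -60.7 on the second.

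The numbers of genes called in the 4 comparisons with medium differed widely. IL1beta raised 3768 genes and lowered 4145, which is 45% of the genes tested. IFNgamma raised 3047 and lowered 3002 (34.4%), and TGFbeta1 raised 2043 and lowered 2478 (25.7%). TNFalpha raised 345 and lowered 121 (2.6%). With the differentiation as a replicate block, the TNFalpha counts were 737 and 545.

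**Figure D2:**
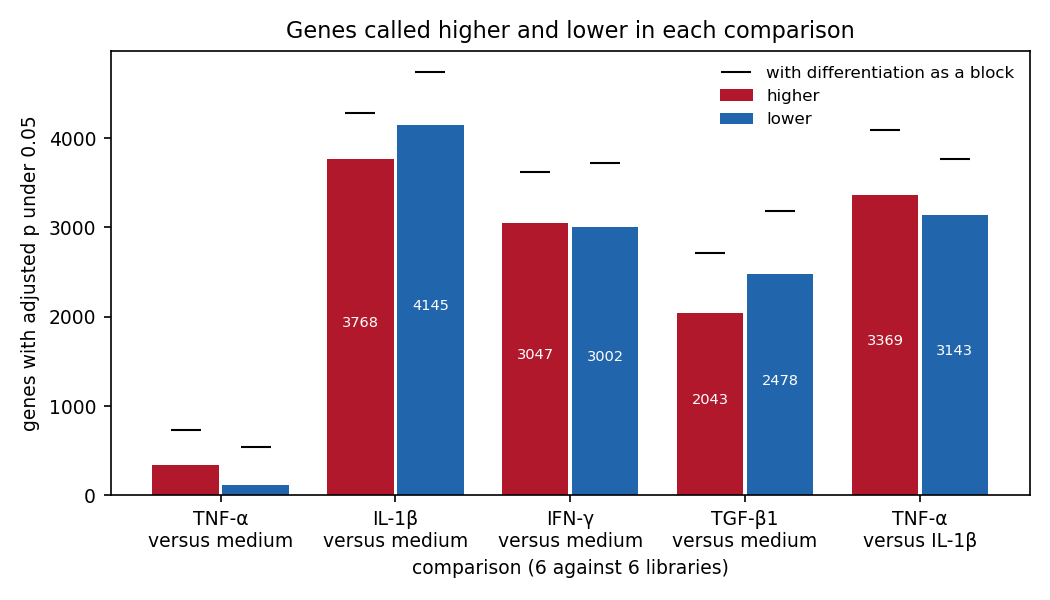
Bars give the number of genes higher or lower at an adjusted p under 0.05 in the 5 comparisons, and the black ticks give the number with the differentiation as a replicate block. The bars for TNFalpha versus medium reach 345 and 121 and those for IL1beta versus medium 3768 and 4145.

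The first comparison asks which transcripts the tumour necrosis factor TNFalpha changes in these macrophages. It raised genes of the metallothionein family, small metal-binding proteins, and a set of inflammatory genes. MT1G rose 31.7-fold, from 1.21 ± 1.12 to 38.1 ± 20.1 CPM (log2 fold change 4.99 ± 0.49, adjusted p = 1.46e-07). CXCL5 (ENSG00000163735), a chemokine that attracts neutrophils, rose 15.6-fold, from 4.5 ± 2.37 to 70.8 ± 31.5 CPM (3.96 ± 0.36, adjusted p = 4.64e-08). SOD2 (ENSG00000112096), the superoxide dismutase of mitochondria, rose 2.51-fold (1.33 ± 0.14, adjusted p = 2.42e-07). Of the 345 raised genes, few rose by much: 101 rose at least 2-fold, and 7 of the 121 lowered genes fell that far.

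Of the 41 tested NF-kB and inflammatory targets, 27 rose, none fell and 14 did not pass the test, and 33 rose when adjusted over the list alone (camera adjusted p = 2.8e-45, and adjusted p = 0.00082 with an estimated correlation). Beside CXCL5 they included TNIP3, an inhibitor of NF-kB activation (3.94 ± 0.44), TNFAIP6, a secreted hyaluronan-binding protein (3.90 ± 0.43), and EBI3, a subunit of the cytokines IL-27 and IL-35 (2.47 ± 0.25). ICAM1, an adhesion receptor for leukocytes, rose 1.42-fold. Of 11 metallothionein-list genes, 9 rose, among them MT1H (4.81 ± 0.47), MT2A (3.72 ± 0.31), MT1F (3.12 ± 0.26) and MT1X (3.00 ± 0.33), and none fell. With adjustment over the list alone 10 rose (adjusted p = 9.9e-24, and adjusted p = 0.0057 with an estimated correlation). Reads of these closely related genes may be shared among them, so the share of each is uncertain.

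Of 21 tested chemokines, 10 rose, 1 fell and 10 did not pass, and 15 rose and 3 fell when adjusted over the list alone (adjusted p = 3e-20, and adjusted p = 0.0027 with an estimated correlation). CCL5 rose 3.86-fold (1.95 ± 0.25) and CCL7, which attracts monocytes, 3.78-fold (1.92 ± 0.32). The chemokine that fell was CXCL9 at -6.97 ± 1.83 (adjusted p = 0.0334), lower in 2 of 6 differentiations. Without the medium library of differentiation 5 its log2 fold change was -1.10 and it was not called, nor was it called with the differentiation as a replicate block (adjusted p = 0.057). Leaving out any 1 differentiation also lost the call, and without differentiation 7 the log2 fold change was -8.32. Of 24 feedback inhibitors and decoys, 8 rose, 1 fell and 15 did not pass, with 11 higher and 3 lower when adjusted over the list alone (adjusted p = 3e-08, and adjusted p = 0.00083 with an estimated correlation). They included ZC3H12A, a ribonuclease that degrades cytokine transcripts (1.02 ± 0.10), and SOCS3, an inhibitor of cytokine receptor signalling (1.01 ± 0.10).

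Further genes rose singly. MIR3142HG, a long non-coding RNA that hosts a microRNA, rose 5.98-fold and C15orf48, a mitochondrial protein of inflamed cells, 3.47-fold. The lectin receptor CLEC4E rose 5.19-fold, the kinase JAK3 2.36-fold, the lipid transfer protein PLTP 2.61-fold, the glucose transporter SLC2A6 2.85-fold and the IL1B transcript itself 1.96-fold (0.97 ± 0.13, adjusted p = 2.08e-05). FTH1, the ferritin heavy chain, rose 1.51-fold. LAMP3, a lysosomal protein of mature dendritic cells, rose 10.7-fold (3.42 ± 0.45). It was 1 of 3 dendritic cell markers of 9 that rose, all 3 also when adjusted over the list alone (adjusted p = 0.006, and adjusted p = 0.184 with an estimated correlation). The matrix protein tenascin, TNC, rose 2.95-fold, THBS1 3.24-fold, the elastase MMP12 2.92-fold and the gelatinase MMP9 1.83-fold. They were among 5 of 28 matrix and protease genes that rose (7 when adjusted over the list alone, adjusted p = 4.5e-06, and adjusted p = 0.302 with an estimated correlation). With the differentiation as a replicate block 13 of the 28 rose and 2 fell, with camera adjusted p = 0.00659 at an estimated correlation. Of the lowered genes, PLD4, an endolysosomal exonuclease, fell 2.47-fold (-1.31 ± 0.19), the zinc transporter SLC39A10 1.82-fold (-0.86 ± 0.13) and the ectonucleotidase ENTPD1 1.63-fold (-0.70 ± 0.14).

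Type I interferon-stimulated genes changed little: 6 of 35 rose and none fell, also when adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.302 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose 2.09-fold (1.06 ± 0.18) and IFITM1, an antiviral membrane protein, 3.65-fold (1.87 ± 0.35). Of 22 genes of cholesterol synthesis, 7 rose, INSIG1 1.28-fold among them (0.35 ± 0.07), and 9 when adjusted over the list alone (adjusted p = 1.8e-12, and adjusted p = 0.0527 with an estimated correlation). Of 10 genes of tryptophan and arginine metabolism, 2 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.00196, and adjusted p = 0.0221 with an estimated correlation). Without the medium library of differentiation 5, 2 of them rose and 0 fell. KYNU (ENSG00000115919), an enzyme of tryptophan breakdown, rose 1.34-fold (0.42 ± 0.07). None of the 15 class II presentation genes, the 13 mitochondrial transcripts or the 21 ribosomal protein genes passed the test. Adjusted over the list alone, 1 class II gene, 2 mitochondrial transcripts and no ribosomal protein gene were lower, and 5, 3 and none with the differentiation as a replicate block. Their list medians were -0.33, -0.19 and -0.11, with adjusted p = 0.0181, 5.2e-06 and 0.00018, and adjusted p = 0.639, 0.276 and 0.673 with an estimated correlation. Smaller groups moved little in the fit without the replicate block. Of 20 class I presentation genes 1 rose (2 over the list alone, adjusted p = 0.0714). Of 22 glycolysis and hypoxia genes 1 rose (3 over the list alone, adjusted p = 0.0022, and adjusted p = 0.162 with an estimated correlation). Of 19 oxidative burst and iron genes 3 rose and 1 fell (4 and 2 over the list alone, adjusted p = 0.027, and adjusted p = 0.302 with an estimated correlation). Of 22 genes of LXR and lipid handling 1 rose and 1 fell (2 and 5 over the list alone, adjusted p = 0.0162, and adjusted p = 0.341 with an estimated correlation). With the differentiation as a replicate block, 8 glycolysis and hypoxia genes rose and 0 fell (camera adjusted p = 1.6e-05, and adjusted p = 0.0563 with an estimated correlation). In the LXR list 2 then rose and 8 fell (camera adjusted p = 1.7e-05, and adjusted p = 0.024 with an estimated correlation). Of 20 apoptosis genes 2 rose, also over the list alone (adjusted p = 0.0347, and adjusted p = 0.154 with an estimated correlation). Without the medium library of differentiation 5 the oxidative burst list had 3 higher and 0 lower (adjusted p = 0.145) and the apoptosis list 1 higher (adjusted p = 0.0503). The class I list then had adjusted p = 0.00956, and adjusted p = 0.486 with an estimated correlation. The cholesterol list then had adjusted p = 0.0267 with an estimated correlation. With the differentiation as a replicate block, 4 further lists passed: TGF-beta-dependent tissue macrophage genes (adjusted p = 0.0985 before and 0.0291 after), pattern recognition (0.0616 and 0.0444), cell cycle (0.145 and 0.0253) and pluripotent cell markers (0.0607 and 0.006). With the replicate block none of the 4 passed at adjusted p = 0.089, 0.183, 0.661 and 0.0635 with an estimated correlation. The receptor transcripts TNFRSF1A (-0.01 ± 0.05, adjusted p = 0.985) and TNFRSF1B (0.07 ± 0.06, adjusted p = 0.735) did not pass the test.

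The TNFalpha counts rest on single differentiations more than the others do. Without differentiation 3 there were 220 higher and 47 lower genes, without differentiation 5 there were 77 lower and without differentiation 7 there were 59 lower.

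The comparison of IL1beta with medium asks the same for interleukin-1, and it gave the largest response by the number of genes called. TNFAIP3 (ENSG00000118503), a ubiquitin-editing inhibitor of NF-kB, rose 19-fold, from 29.9 ± 4.35 to 567 ± 55.1 CPM (4.25 ± 0.20, adjusted p = 1.44e-16). TNFAIP6 rose 163-fold (7.35 ± 0.39), CLEC4E 134-fold (7.06 ± 0.23) and CXCL5 77.6-fold (6.28 ± 0.39). F13A1 (ENSG00000124491), a clotting factor subunit, fell 29.7-fold, from 31.9 ± 10.7 to 1.08 ± 0.385 CPM (-4.89 ± 0.39, adjusted p = 1.57e-11), and the iron exporter SLC40A1 fell 25.8-fold (-4.69 ± 0.32).

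Of 41 NF-kB and inflammatory targets, 38 rose, none fell and 3 did not pass, also when adjusted over the list alone (adjusted p = 1e-34, and adjusted p = 0.0025 with an estimated correlation). Beside those named, TNIP3 rose 141-fold and NFKBIA, the inhibitor of NF-kB, 6.87-fold (2.78 ± 0.15). Of 21 chemokines, 19 rose and none fell, with 20 higher when adjusted over the list alone (adjusted p = 5.3e-15, and adjusted p = 0.0066 with an estimated correlation). CCL5 rose 56.5-fold (5.82 ± 0.26) and CCL8 44.8-fold (5.48 ± 0.24). The cytokine transcripts IL1A (3.84 ± 0.29), IL1B (3.10 ± 0.14) and TNF (2.26 ± 0.17) rose. Of 24 feedback inhibitors and decoys, 15 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.00054, and adjusted p = 0.0172 with an estimated correlation, or 0.0575 with the replicate block as well).

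Of 35 type I interferon-stimulated genes, 34 rose and 1 did not pass, and 35 rose when adjusted over the list alone (adjusted p = 5.4e-25, and adjusted p = 0.0241 with an estimated correlation, or 0.0575 with the replicate block as well). IFI44L rose 38.1-fold (5.25 ± 0.42), USP18, which trims ISG15 from proteins, 32.4-fold (5.02 ± 0.31), OAS2, an antiviral enzyme, 31.3-fold (4.97 ± 0.40) and OASL 26.2-fold (4.71 ± 0.40). CD274, the checkpoint ligand PD-L1, rose 10.6-fold (3.40 ± 0.25). The chemokine CXCL10 rose by 4.88 ± 0.66, CXCL11 by 5.77 ± 0.52 and the tryptophan-degrading enzyme IDO1 by 5.04 ± 0.63. Without the medium library of differentiation 5 these were 8.72, 7.27 and 8.63. Of 20 class I presentation genes, 15 rose and 1 fell, also when adjusted over the list alone (adjusted p = 2.1e-06, and adjusted p = 0.119 with an estimated correlation), with the peptide transporter gene TAP1 2.87-fold higher and TAPBP 2.22-fold.

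Of 10 genes of tryptophan and arginine metabolism, 6 rose and none fell, also when adjusted over the list alone (adjusted p = 7.7e-05, and adjusted p = 0.0058 with an estimated correlation). KYNU rose 7.02-fold (2.81 ± 0.07), the kynurenine hydroxylase KMO 8.19-fold (3.03 ± 0.11) and ASS1, of arginine synthesis, 13.3-fold (3.74 ± 0.43). Of 22 genes of cholesterol synthesis, 20 rose and 2 fell, also when adjusted over the list alone (adjusted p = 3e-08, and adjusted p = 0.143 with an estimated correlation), among them SQLE 2.07-fold and LSS 1.97-fold. Of 11 metallothionein-list genes, 10 rose, also when adjusted over the list alone (adjusted p = 7.2e-10, and adjusted p = 0.0737 with an estimated correlation). MT1G rose 277-fold and MT1H 259-fold. SOD2 rose 15.8-fold, NR1H3, the sterol-sensing receptor LXR alpha, 11.5-fold and SLC2A6 31.1-fold. Of 22 genes of LXR and lipid handling, 3 rose and 13 fell, with 14 lower when adjusted over the list alone (adjusted p = 0.0424, and adjusted p = 0.469 with an estimated correlation). TREM2, a lipid-sensing receptor, fell 3.68-fold (-1.88 ± 0.14).

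Of 20 tested TGF-beta-dependent tissue macrophage genes, 14 fell, 4 rose and 2 did not pass, also when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.0066 with an estimated correlation). The adhesion receptor ADGRG1 fell 48.7-fold (-5.61 ± 0.59), the fractalkine receptor CX3CR1 12.8-fold (-3.68 ± 0.35) and GAS6, a bridge for uptake of dead cells, 10.7-fold (-3.42 ± 0.26). Of 24 alternative activation and scavenging genes, 16 fell and 5 rose, also when adjusted over the list alone (adjusted p = 0.00074, and adjusted p = 0.154 with an estimated correlation), including LYVE1 7.02-fold (-2.81 ± 0.35) and IGF1 6.84-fold (-2.77 ± 0.35). Of 27 lysosome and phagocytosis genes, 15 fell and 6 rose, with 7 higher when adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.523 with an estimated correlation), and the Fc receptor FCGR2A fell 4.11-fold (-2.04 ± 0.06). CEBPA, a transcription factor of myeloid cells, fell 5.04-fold, HPGDS, which makes prostaglandin D, 15.4-fold and the protocadherin PCDH12 68.2-fold. Of 24 cell cycle genes, 12 fell and none rose, with 14 lower when adjusted over the list alone (adjusted p = 0.00196, and adjusted p = 0.68 with an estimated correlation), and TOP2A fell 2.1-fold. Of 21 ribosomal protein genes, 19 fell, by little (RPS18, -0.40 ± 0.10), and 20 when adjusted over the list alone (adjusted p = 0.00054, and adjusted p = 0.68 with an estimated correlation).

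Of 20 T-cell costimulation and checkpoint genes, 11 rose and 5 fell, with 12 and 6 when adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.0222 with an estimated correlation, or 0.059 with the replicate block as well). SLAMF1 rose 30.4-fold and SLAMF7 12.1-fold. Of 28 genes for targets of drugs used in immune disease, 15 rose and 7 fell, with 8 lower when adjusted over the list alone (adjusted p = 0.0447, and adjusted p = 0.0658 with an estimated correlation). Without the medium library of differentiation 5 this list had adjusted p = 0.0503. JAK3 rose 17.7-fold (4.15 ± 0.15) and ITGB7, an integrin subunit, fell 5.16-fold (-2.37 ± 0.11). Of 28 matrix and protease genes, 14 rose and 1 fell, with 2 lower when adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.571 with an estimated correlation), and TNC rose 14.3-fold (3.84 ± 0.21). A few genes nearly silent in medium rose furthest. LAD1, an anchoring filament protein, had 4223 counts over the 6 IL1beta libraries and 1 over the 6 medium libraries, a ratio of 4111 (95% interval 737.4 to 162400). The adhesion molecule VCAM1 had 1527 and 3 counts, a ratio of 495.5 (169.2 to 2405), and the potassium channel KCNJ10 1274 and 2 counts, a ratio of 620.1 (171.3 to 5126). MT1A, with no count in medium, was at least 82.1-fold higher. These intervals and bounds cover counting error only. Of 34 TGF-beta and SMAD targets 10 rose and 15 fell, with 16 lower over the list alone (adjusted p = 0.28), and of 15 class II presentation genes 4 rose and 2 fell, also over the list alone (adjusted p = 0.37). Of 20 apoptosis genes 10 rose and 4 fell, also over the list alone (adjusted p = 0.0577), and with the differentiation as a replicate block this list had adjusted p = 0.0305, and adjusted p = 0.0575 with an estimated correlation. CFLAR, an inhibitor of cell death, rose 2.57-fold (1.36 ± 0.08).

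**Figure D3:**
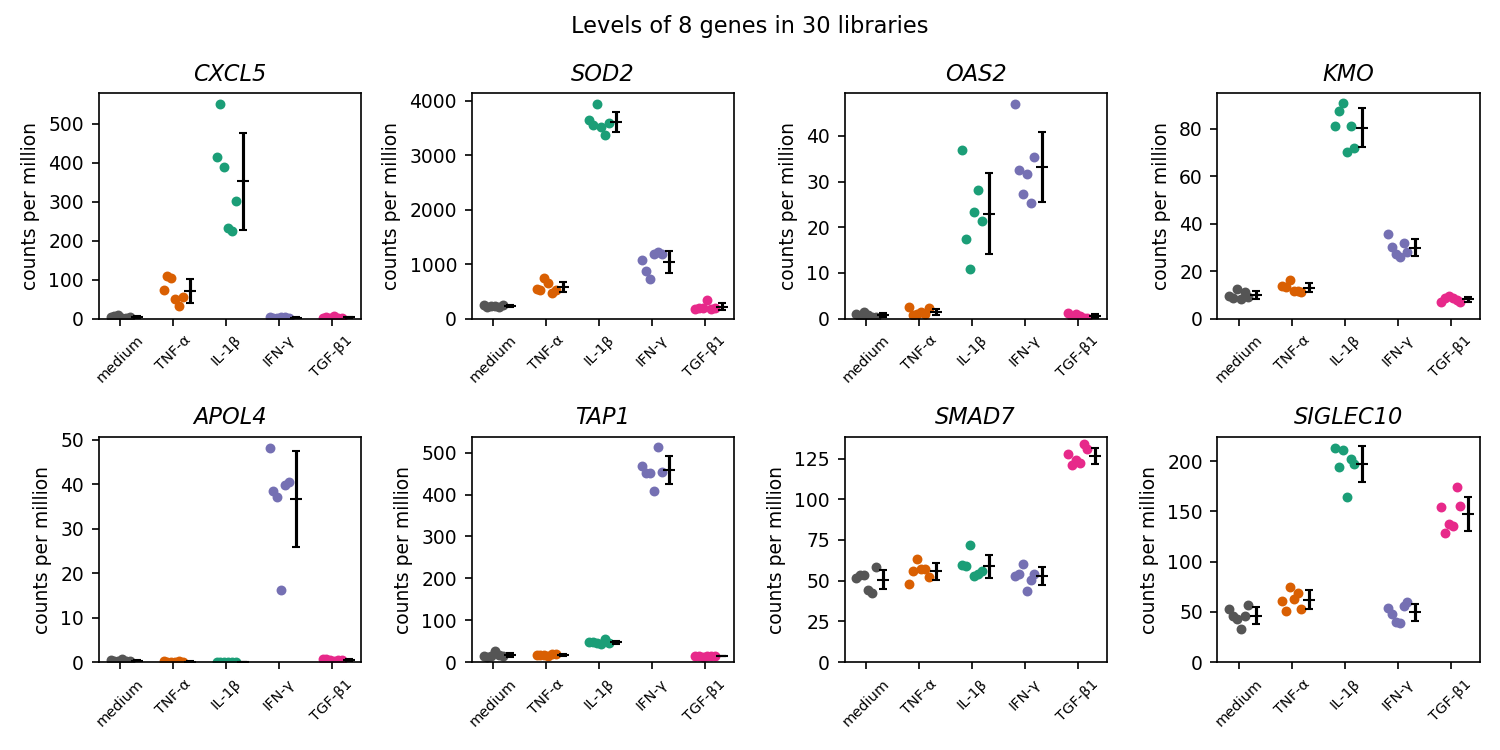
Levels in CPM (y axes) of 8 genes in each of the 30 libraries (points), with the mean and SD of the 6 libraries of each group (bars). CXCL5 has a mean of 4.5 CPM in medium, 70.8 with TNFalpha and 352 with IL1beta, while SIGLEC10 has a mean of 46.1 CPM in medium and 148 with TGFbeta1.

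TNFalpha and IL1beta both signal through NF-kB, and their direct comparison asks where the responses differ. At the doses used, 3369 genes were higher and 3143 lower with TNFalpha than with IL1beta. Most of the TNFalpha response lay within the IL1beta response. Of the 345 genes that TNFalpha raised, 337 were also raised by IL1beta (73.9 if the calls were independent), 1 was lowered and 7 did not pass. The direct contrast found 292 of the 345 higher with IL1beta, 9 higher with TNFalpha and 44 that did not pass, and their median log2 fold change against medium was 0.61 with TNFalpha and 1.57 with IL1beta. Of the 121 genes that TNFalpha lowered, 112 were lowered by IL1beta (28.5 if independent). Of the 1080 genes that IL1beta raised at least 2-fold, 239 passed the test with TNFalpha. These overlaps were counted in the fit without the replicate block. With the block TNFalpha raised 737 genes in place of 345, so the number that passes depends on the fit. The changes with TNFalpha and with IL1beta use the same 6 medium libraries. With split controls the 2 cytokines raised 101.5 genes in common (15.1 if independent) and lowered 9 (1.8 if independent), as medians over 20 splits.

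Of 41 NF-kB and inflammatory targets, 37 were lower with TNFalpha and none was higher, also when adjusted over the list alone (adjusted p = 7.5e-36, and adjusted p = 0.0023 with an estimated correlation). BIRC3, an inhibitor of apoptosis, was 17.7-fold lower (-4.14 ± 0.23), CCL5 14.6-fold (-3.87 ± 0.23) and TNFAIP3 10.4-fold (-3.38 ± 0.19). Of 35 type I interferon-stimulated genes, 33 were lower and none was higher, with 34 lower when adjusted over the list alone (adjusted p = 1.2e-27, and adjusted p = 0.0181 with an estimated correlation, or 0.0502 with the replicate block as well). IFIT2, an antiviral RNA-binding protein, was 21.7-fold lower (-4.44 ± 0.21) and CXCL10 213-fold (-7.73 ± 0.85). KMO was 6.23-fold lower with TNFalpha and KYNU 5.24-fold. Of the 4145 genes that IL1beta lowered, 3141 were higher with TNFalpha than with IL1beta, none was lower and 1004 did not pass. The 4145 were chosen as low in the same IL1beta libraries, so most would be higher with TNFalpha even without a response to it. Higher with TNFalpha were F13A1 21.6-fold (4.43 ± 0.38), SLC40A1 12.7-fold (3.67 ± 0.32), HPGDS 9.57-fold (3.26 ± 0.24) and the mannose receptor MRC1 4.2-fold (2.07 ± 0.11). Of 24 alternative activation and scavenging genes, 16 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 2.8e-05, and adjusted p = 0.0713 with an estimated correlation). Of 20 TGF-beta-dependent tissue macrophage genes, 14 were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.00069, and adjusted p = 0.0058 with an estimated correlation). Of 21 chemokines 18 were lower (adjusted p = 3.3e-14, and adjusted p = 0.008 with an estimated correlation), and of 11 metallothionein-list genes 10 (adjusted p = 7.9e-12, and adjusted p = 0.0474 with an estimated correlation). Both counts are the same when adjusted over the list alone. Of 20 class I presentation genes 16 were lower, and 17 lower and 1 higher over the list alone (adjusted p = 9.7e-07, and adjusted p = 0.104 with an estimated correlation). Of 20 T-cell costimulation and checkpoint genes 12 were lower and 5 higher, also over the list alone (adjusted p = 0.0021, and adjusted p = 0.0157 with an estimated correlation). Among 22 genes of cholesterol synthesis 16 were lower and 2 higher, with 17 lower over the list alone (adjusted p = 2e-05, and adjusted p = 0.286 with an estimated correlation). Of 24 cell cycle genes 8 were higher and none lower, with 7 higher over the list alone (adjusted p = 0.0034, and adjusted p = 0.68 with an estimated correlation). Among 22 genes of LXR and lipid handling 8 were higher and 3 lower, with 9 higher over the list alone (adjusted p = 0.203), and with the differentiation as a replicate block this list had adjusted p = 0.0165, and adjusted p = 0.183 with an estimated correlation. Of 21 ribosomal protein genes 4 were higher, and none over the list alone (adjusted p = 0.019, and adjusted p = 0.788 with an estimated correlation), and with the replicate block 18 were higher. Of 15 class II presentation genes 6 were lower and 1 higher, with 7 lower over the list alone (adjusted p = 0.0372, and adjusted p = 0.675 with an estimated correlation), and of 27 lysosome and phagocytosis genes 15 were higher and 5 lower, with 7 lower over the list alone (adjusted p = 0.0206, and adjusted p = 0.516 with an estimated correlation). Of 24 feedback inhibitors and decoys 12 were lower and 5 higher, with 13 and 7 over the list alone (adjusted p = 0.00151, and adjusted p = 0.0257 with an estimated correlation, or 0.0635 with the replicate block as well). Of 28 drug target genes 14 were lower and 7 higher, with 8 higher over the list alone (adjusted p = 0.0148, and adjusted p = 0.0239 with an estimated correlation).

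**Figure D4:**
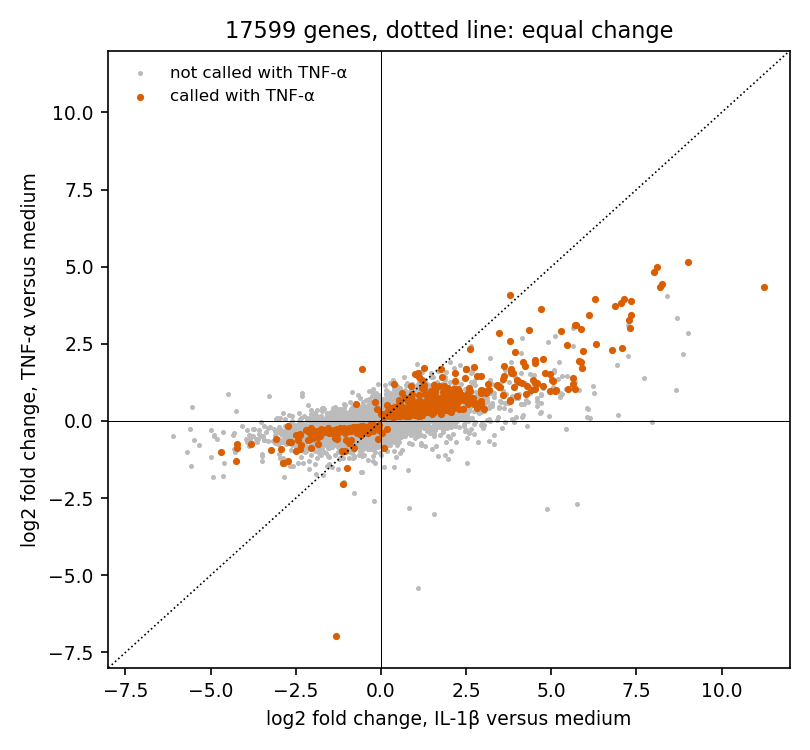
Each point is 1 of the 17599 genes tested, with its log2 fold change against medium with IL1beta (x axis) and with TNFalpha (y axis). Orange points passed the test with TNFalpha, 345 higher and 121 lower, and the dotted line marks equal change.

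The comparison of IFNgamma with medium asks which transcripts the type II interferon changes. TAP1 (ENSG00000168394) rose 27.9-fold, from 16.4 ± 5.25 to 458 ± 33.7 CPM (4.80 ± 0.13, adjusted p = 8.13e-23). CIITA, the master regulator of class II genes, rose 41.7-fold, from 6.66 ± 2.51 to 279 ± 65.2 CPM (5.38 ± 0.27, adjusted p = 9.01e-16), and the apolipoprotein gene APOL4 rose 112-fold (6.80 ± 0.32). LYVE1 (ENSG00000133800), a hyaluronan receptor of tissue macrophages, fell 15.1-fold (-3.91 ± 0.38, adjusted p = 1.6e-09).

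The medium library of differentiation 5 held more transcripts of several genes raised by IFNgamma than the other 5 medium libraries, which lowers their fitted folds. GBP1, a guanylate-binding protein, had 464 counts in it and 64 over the other 5. Its log2 fold change was 7.59 ± 0.61, and 10.31 without that library. For GBP5 it was 8.53 ± 0.44 and 9.83, for CXCL9 7.76 ± 0.80 and 13.63, for CXCL10 7.54 ± 0.72 and 11.37, for IDO1 7.34 ± 0.61 and 10.93, and for SOCS1, an inhibitor of interferon signalling, 7.14 ± 0.41 and 8.12. GBP4 had no count in those 5 libraries and 26915 over the 6 IFNgamma libraries, at least 7021-fold higher, against a fitted 7.89 ± 0.54 with all 6.

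All 15 tested class II presentation genes rose (adjusted p = 1.8e-21, and adjusted p = 0.0066 with an estimated correlation), and all 20 class I presentation genes rose (adjusted p = 1.2e-37, and adjusted p = 0.00027 with an estimated correlation). Both counts are the same when adjusted over the list alone. HLA-DOA rose 58.3-fold (5.87 ± 0.37), HLA-DPA1 36.4-fold (5.18 ± 0.39) and NLRC5, the regulator of class I genes, 13.9-fold (3.79 ± 0.13). Reads of the HLA genes may be shared among relatives, so their single values are uncertain. Of 35 type I interferon-stimulated genes, 34 rose, also when adjusted over the list alone (adjusted p = 1.7e-37, and adjusted p = 0.0066 with an estimated correlation), with SAMD9L 53.9-fold and IFITM1 47.9-fold higher. Of 20 T-cell costimulation and checkpoint genes, 11 rose and 3 fell, also when adjusted over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.00083 with an estimated correlation). CD274 rose 45.7-fold (5.51 ± 0.26), PDCD1LG2, the ligand PD-L2, 22.6-fold (4.50 ± 0.23) and SLAMF7 13.7-fold (3.78 ± 0.28).

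Of 41 NF-kB and inflammatory targets, 31 rose and 4 fell, also when adjusted over the list alone (adjusted p = 1.3e-12, and adjusted p = 0.0595 with an estimated correlation). The receptor CD40 rose 9.43-fold and IL6 8.24-fold. Of 21 chemokines, 15 rose and none fell, also when adjusted over the list alone (adjusted p = 9.2e-07, and adjusted p = 0.0923 with an estimated correlation), CCL8 31.7-fold among them. Of 20 apoptosis genes, 12 rose and 1 fell, with 14 higher when adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.00082 with an estimated correlation). The death ligand TNFSF10, also called TRAIL, rose 13-fold (3.70 ± 0.19) and FAS, a death receptor, 3.12-fold (1.64 ± 0.12). Of 24 feedback inhibitors and decoys, 19 rose and 3 fell, also when adjusted over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.0025 with an estimated correlation). Of 26 pattern recognition and inflammasome genes, 15 rose and 2 fell, also when adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.0066 with an estimated correlation). TLR8, a sensor of RNA, rose 5.31-fold and MEFV, the pyrin gene, 4.65-fold. Of 28 drug target genes, 13 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.0039, and adjusted p = 0.0091 with an estimated correlation), with TNF 6.61-fold, TNFSF13B (the B-cell factor BAFF) 7.08-fold and JAK3 6.25-fold higher. Of 10 genes of tryptophan and arginine metabolism, 6 rose, also when adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.0027 with an estimated correlation), with WARS1, the tryptophan tRNA synthetase, 17.5-fold higher (4.13 ± 0.11).

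Of 24 cell cycle genes, 18 fell and none rose, also when adjusted over the list alone (adjusted p = 5.3e-12, and adjusted p = 0.225 with an estimated correlation). The centromere protein CENPF fell 2.67-fold (-1.41 ± 0.14) and PLK1, a mitotic kinase, 2.46-fold (-1.30 ± 0.09). Of 24 alternative activation and scavenging genes, 11 fell and 4 rose, also when adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.366 with an estimated correlation), with F13A1 5.35-fold and SELENOP, a selenium carrier, 2.96-fold lower. Of 28 matrix and protease genes, 10 fell and none rose, also when adjusted over the list alone (adjusted p = 0.0398, and adjusted p = 0.709 with an estimated correlation), with THBS1 3.11-fold and SPARC 2.4-fold lower. Of 11 metallothionein-list genes, 7 rose, also when adjusted over the list alone (adjusted p = 0.0047, and adjusted p = 0.516 with an estimated correlation), with MT2A 32-fold higher (5.00 ± 0.31). The proteoglycan VCAN fell 5.87-fold, the histamine receptor HRH1 5.7-fold and ATP6V0D2, a proton pump subunit, 5.51-fold. Of 6 endothelial markers, 2 fell, also when adjusted over the list alone (adjusted p = 0.0607). With the differentiation as a replicate block this list had adjusted p = 0.0153, and adjusted p = 0.0522 with an estimated correlation. Of 21 ribosomal protein genes, 3 fell, and 1 when adjusted over the list alone (adjusted p = 0.0302, and adjusted p = 0.807 with an estimated correlation). With the replicate block 12 fell and 1 rose.

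The comparison of TGFbeta1 with medium asks which transcripts this growth factor changes. Of 24 feedback inhibitors and decoys, 5 rose and 2 fell, with 3 lower when adjusted over the list alone (adjusted p = 0.498). SMAD7 (ENSG00000101665) rose 2.51-fold, from 50.5 ± 5.99 to 127 ± 5.06 CPM (1.32 ± 0.08, adjusted p = 1.47e-13), SMAD6 3.08-fold (1.62 ± 0.10, adjusted p = 1.66e-13) and PMEPA1 3.08-fold (1.63 ± 0.21, adjusted p = 4.34e-07). TJP1, a tight junction protein, rose 19.2-fold (4.27 ± 0.38), and RGS16, a regulator of G-protein signalling, 18.2-fold (4.19 ± 0.21). WNT5A, a secreted Wnt ligand, rose 10.2-fold. The thrombin receptor gene F2RL3 fell 8.51-fold (-3.09 ± 0.28) and LYVE1 5.5-fold (-2.46 ± 0.34).

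Of 34 tested TGF-beta and SMAD targets, 20 rose, 4 fell and 10 did not pass, also when adjusted over the list alone (adjusted p = 4.1e-12, and adjusted p = 0.0068 with an estimated correlation). The member that changed most fell: SMAD3, which carries the signal of the receptor, at -3.98 ± 0.41 (adjusted p = 1.07e-08), and -4.82 without differentiation 4. VEGFA, a vascular growth factor, rose 2.2-fold (1.14 ± 0.12), and the receptor TGFBR1 rose 1.55-fold (0.63 ± 0.06). Of 20 TGF-beta-dependent tissue macrophage genes, 8 rose, none fell and 12 did not pass, with 1 lower when adjusted over the list alone (adjusted p = 0.00092, and adjusted p = 0.0059 with an estimated correlation). ADGRG1 rose 4.16-fold (2.06 ± 0.37), OLFML3 3.23-fold (1.69 ± 0.16), the sialic acid receptor SIGLEC10 3.2-fold (1.68 ± 0.12) and the purine receptor P2RY12 2.44-fold (1.29 ± 0.28), all known from microglia. IL1beta lowered ADGRG1 and CX3CR1, and TGFbeta1 raised CX3CR1 2.1-fold (1.07 ± 0.28).

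Of 24 alternative activation and scavenging genes, 14 fell and none rose, with 1 higher and 15 lower when adjusted over the list alone (adjusted p = 2.3e-06, and adjusted p = 0.0415 with an estimated correlation, or 0.0563 with the replicate block as well). F13A1 fell 4.05-fold (-2.02 ± 0.32) and IGF1 2.69-fold (-1.43 ± 0.33). The sialoadhesin SIGLEC1 fell 3.78-fold, the scavenger receptor COLEC12 3.55-fold and the bone morphogenetic protein BMP2 3.74-fold. Of 24 cell cycle genes, 23 fell and none rose, also when adjusted over the list alone (adjusted p = 3.2e-19, and adjusted p = 0.0959 with an estimated correlation). RRM2, of DNA precursor synthesis, fell 1.98-fold (-0.98 ± 0.12) and the cyclin-dependent kinase CDK1 1.84-fold (-0.88 ± 0.12). Of 22 genes of cholesterol synthesis, 8 fell and 1 rose, with 9 lower when adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.662 with an estimated correlation), LSS by 1.32-fold. Of 20 apoptosis genes, 9 fell and 1 rose, with 11 and 2 when adjusted over the list alone (adjusted p = 0.0465, and adjusted p = 0.174 with an estimated correlation). With the differentiation as a replicate block the apoptosis list had adjusted p = 0.104. RIPK3, a kinase of necroptosis, fell 1.44-fold. Of 12 housekeeping genes, 3 fell, also when adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.382 with an estimated correlation), HPRT1 1.35-fold among them.

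The count of lowered chemokines with TGFbeta1 depends on the medium library of differentiation 5. Of 21 chemokines, 8 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.21), and 4 fell without that library. CXCL9 was at -6.93 ± 1.84 (adjusted p = 0.00552, lower in 3 of 6 differentiations), -1.06 without it and -10.36 without differentiation 2. CXCL10 was at -3.72 ± 1.16 (adjusted p = 0.0174, lower in 4 of 6), 0.11 without it and -5.08 without differentiation 2. NLRC5 fell 2.33-fold (-1.22 ± 0.13, adjusted p = 2.87e-08) and CIITA rose 2.21-fold (1.14 ± 0.25), both lasting without that library. The drug target gene S1PR1, a receptor for sphingosine phosphate, fell 3.03-fold (-1.60 ± 0.14), and of the 28 drug target genes 10 rose and 5 fell, with 12 higher when adjusted over the list alone (adjusted p = 0.127). Of 11 metallothionein-list genes, 5 fell, with 7 when adjusted over the list alone (adjusted p = 0.0714). With the differentiation as a replicate block the adjusted p was 0.014, and adjusted p = 0.389 with an estimated correlation, and without the medium library of differentiation 5 it was 0.0418 and adjusted p = 0.668 with an estimated correlation.

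**Figure D5:**
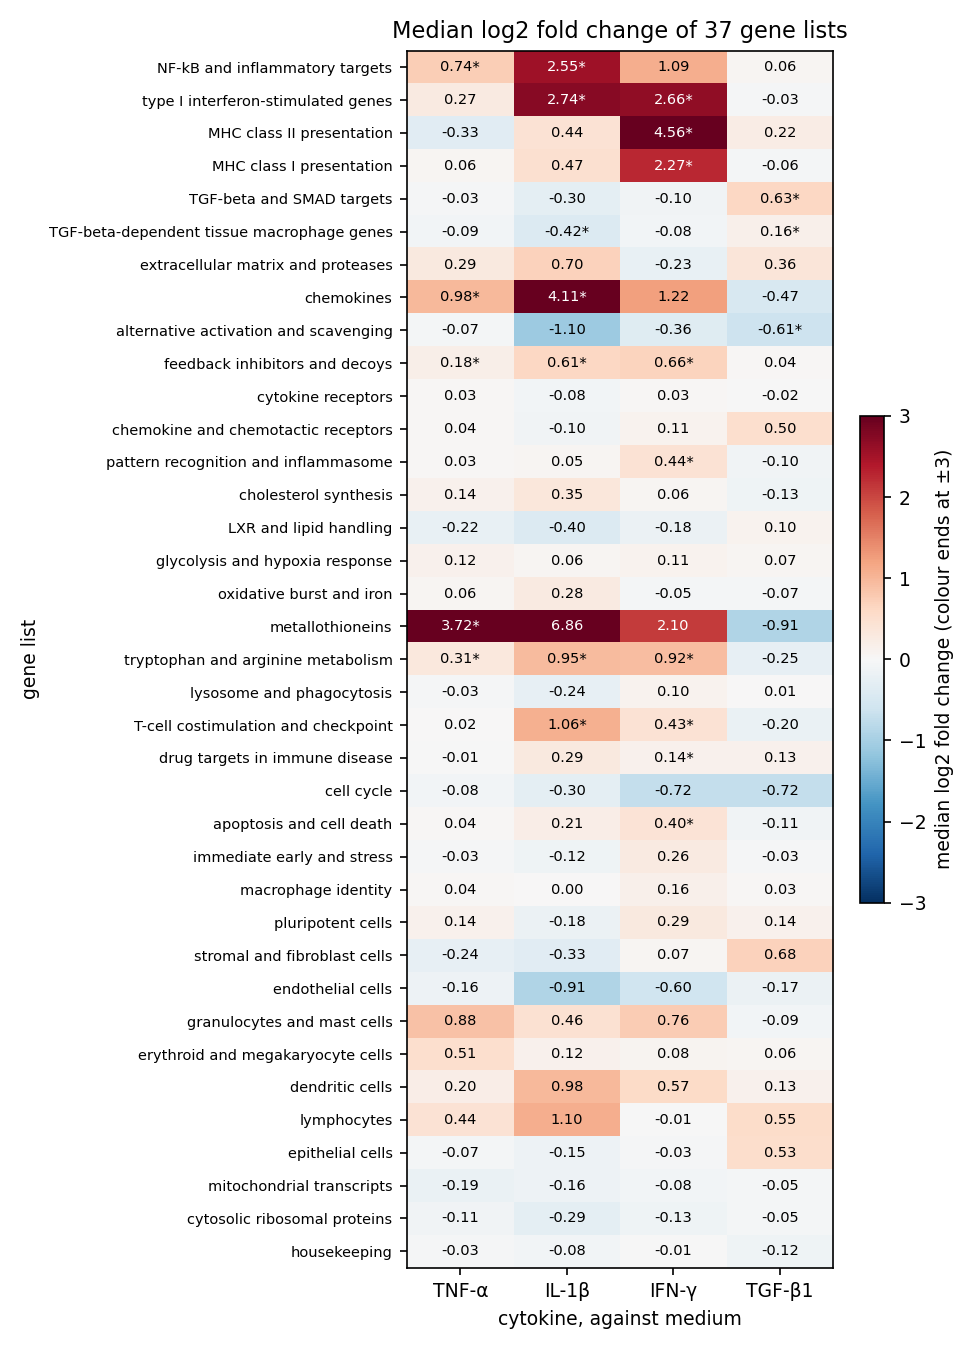
Median log2 fold change against medium of the tested members of each of 37 gene lists (rows) with each cytokine (columns), on a colour scale that ends at -3 and 3, with an asterisk where camera gave an adjusted p under 0.05 with an estimated correlation. Medians use fitted values, also for genes near 0 counts such as MT1A, and the strongest columns for NF-kB and type I interferon lists are IL1beta (2.55 and 2.74) and IFNgamma (1.09 and 2.66).

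Genes raised selectively were those higher than in medium and higher than with each of the other 3 cytokines. IL1beta had 1743 such genes (46.3% of those it raised), IFNgamma 1458 (47.9%) and TGFbeta1 1042 (51%). KCNJ10 and VCAM1 were among the largest for IL1beta, GBP1 and GBP5 for IFNgamma, and TJP1, RGS16, the calcium channel gene CACNA1G (9.54-fold) and TLCD2 (8.09-fold) for TGFbeta1. TNFalpha had 3: the Wnt receptor FZD3 (0.61 ± 0.16, adjusted p = 0.0299), SLAMF9, a receptor of the SLAM family (1.68 ± 0.45, adjusted p = 0.0347), and FCRLB, an Fc receptor-like protein (0.51 ± 0.13, adjusted p = 0.0319). With the differentiation as a replicate block TNFalpha had 19, these 3 included. The count was 0 without differentiation 3 or 7, and 1 without differentiation 2 or without the medium library of differentiation 5. It was 2 without differentiation 4 and 3 without differentiation 5 or 6. Other genes entered some of these counts, since the losses given next would leave fewer without differentiation 4, 5 or 6. Against medium, FZD3 lost its call without differentiation 3 (0.58, adjusted p = 0.189), 4 or 7. SLAMF9 lost it without differentiation 2, 3, 5 or 7 or the medium library of differentiation 5 (1.49, adjusted p = 0.0994), and FCRLB without that library (0.42, adjusted p = 0.0995) or any differentiation but 5.

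Across genes, which are not independent replicates, the log2 fold changes with TNFalpha and IL1beta had r = 0.64 (covariance 0.1477). Both share the 6 medium libraries, which alone gave r = 0.50 and a covariance of 0.0155 in simulated groups without a change. With the controls split so that each cytokine had its own 3 medium libraries, r was 0.47 (range 0.44 to 0.51 over 20 splits). IL1beta and IFNgamma had r = 0.41 (covariance 0.2208), and 0.35 with split controls. They raised 1362 genes in common (652.4 if independent) and lowered 1543 (707 if independent). TNFalpha and IFNgamma had r = 0.26 (0.15 with split controls), with a covariance of 0.0494 against 0.0156 in the simulated groups. They raised 212 genes in common (59.7 if independent) and lowered 69 (20.6 if independent). In opposite directions, 28 rose with TNFalpha and fell with IFNgamma (58.8 if independent), and 21 did the reverse (20.9). The simulated r of 0.50 is for groups that differ by noise only. An r below it therefore does not show less agreement than between unchanged groups. For TGFbeta1, r was 0.09 with TNFalpha, 0.04 with IL1beta and 0.00 with IFNgamma, and -0.03, 0 and -0.05 with split controls.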

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

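Each gene named in the report was checked for a differentiation whose difference between the groups lay far from the other 5, and this check was planned. The tests of the 3 patterns below were chosen after the results were seen, as were the other splits of the samples for TNFalpha, IL1beta and IFNgamma against medium, while the gene counts for TGFbeta1 and for TNFalpha against IL1beta were planned before their results were seen. For the lists of all comparisons the way of adjusting p in the splits was chosen after.

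Dixon's ratio is the gap between an extreme value and its neighbour over the whole range. It was above the 95% critical value for 6 samples for 20 of 191 differences and for none of the 5 sets of library totals. Chance alone marks about 1 in 20 groups, here 9.8. In 12 of the 20 the extreme differentiation was number 5. With IFNgamma these were APOL4 (0.63), CXCL10 (0.75), CXCL9 (0.66), GBP4 (0.91), GBP5 (0.72), TAP1 (0.83) and WARS1 (0.94). CXCL9 differed by 4.65 on the log2 scale in differentiation 5 and by 11.09 to 14.45 in the others, and WARS1 by 3.54 against 4.22 to 4.26. With IL1beta they were CD274 (0.7), CXCL10 (0.73), IDO1 (0.79) and TAP1 (0.82), and with TGFbeta1 CXCL10 (0.63). In differentiation 7, the ratio was 0.66 for MT2A and 0.65 for ENTPD1 with TNFalpha, and 0.81 for ADGRG1, 0.69 for TAPBP and 0.75 for TNFRSF1B with IL1beta. In differentiation 4 it was 0.93 for CXCL5 and 0.63 for IL1A with IL1beta, and 0.67 for ATP6V0D2 with IFNgamma. ADGRG1 fell by 6.69 in differentiation 7 and by 4.74 to 5.1 in the others.

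The medium library of differentiation 5 held transcripts of genes raised by IFNgamma. Over 10 genes nearly silent in the other medium libraries it held a median of 3.52% of their level with IFNgamma (0.766 to 5.73), and over 42 other genes raised by IFNgamma, kept apart for the test, a median of 2.84% (-0.483 to 8.01), where the other 5 medium libraries had medians of -0.808 to 0.301. A mixture of IFNgamma-treated cells or their RNA into this culture or library needs one share over all such genes. The medians are alike, but the shares differ between genes, and whether by more than between IFNgamma libraries depends on the reference. Over the 10 genes the 90th percentile of the share was 3.11 times the 10th against the IFNgamma library of differentiation 5, where the other 5 IFNgamma libraries gave ratios of 1.61 to 3.59. Against the mean of the 6 IFNgamma libraries it was 5.45 times, where single libraries against the other 5 gave 1.49 to 2.77. Of the 42 genes none lay off the 3.52% by more than 2.78 standard deviations of the same share in the other 5 medium libraries, and 11 lay off 0 by as much. Reads of a single IFNgamma library of this series are argued against by a chi-square per degree of freedom of at least 5.77 (up to 28.35), and material of all 4 cytokine groups by 4 genes raised by IL1beta alone, with a median share of 0.176% (-0.257 to 0.609). A mixture and a weak response of the cells themselves, the biological explanation, which was not tested, cannot be told apart, as the 2 references disagree and counts of the 10 genes were as few as 3.

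IL1beta raised 34 of 35 type I interferon-stimulated genes. Material of the IFNgamma group in the IL1beta libraries is argued against: 29 of these genes reached a median of 67.5% of their level with IFNgamma, and 12 genes silent in medium and raised by IFNgamma only 2.48%. Type I interferon made in the IL1beta cultures may explain the pattern, as a hypothesis only. IFNB1 had 7 counts in 4 of the 6 IL1beta libraries, at most 3 in any library, and none in the other 24 (Fisher's exact test, p = 0.00055), and the gene was picked after values had been seen. IFNA1, IFNL1, IFNL2 and IFNL3 had 0 counts in all 30 libraries.

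The TNFalpha response was smaller than the IL1beta response and lay mostly within it. IL1beta material in the TNFalpha libraries would give all genes one share of the IL1beta level, but over 29 genes the 90th percentile of that share was 33 times the 10th (11.6% and 0.352%, median 3.75%), where single IL1beta libraries gave ratios of 1.79 to 2.53. Fewer counts are argued against by a ratio of the mean totals, TNFalpha over IL1beta, of 1.01. The 2 cytokines were given at the same dose by mass, so a difference in that dose is not an explanation. A difference in their activity at that dose or in their receptors could explain the smaller response and was not tested.

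Other splits of the same libraries show whether chance can give as many calls. For each comparison the 2 groups were exchanged within differentiations in all 32 ways that part every pair, the real one included, and 28 further splits that do not part the pairs were drawn, which also put differences between differentiations between the groups. For TNFalpha against medium, 1 of 32 splits, the real one, gave as many genes higher (345, highest other 1), lower (121, highest other 1) and raised selectively (3, highest other 0). For IL1beta against medium it was also 1 of 32, with 3768 higher, 4145 lower (highest other 2085 for each) and 1743 raised selectively (highest other 848). IFNgamma against medium had 1 of 32, with 3047 and 3002 (highest other 1633) and 1458 (highest other 623). TGFbeta1 against medium had 1 of 32, with 2043 and 2478 (highest other 856) and 1042 (highest other 359), and for TNFalpha against IL1beta it was 1 of 32 with 3369 and 3143 (highest other 1638). Splits that do not part the pairs reached at most 14, 2554, 1200, 1982 and 1294 genes in 1 direction in these comparisons. This argues against chance for each count of genes higher and lower, though 1 of 32 is the smallest share that these splits can give. The splits exchange no other cytokine, so for the selective counts this holds only for the difference from medium. For TNFalpha the other splits left at most 1 gene higher than medium.

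For gene lists it depends on the correlation. The p values were adjusted over all 185 list tests, with those of the other comparisons kept as they are. With a preset correlation, TNFalpha against medium had 17 lists and the highest other split 15, so that 1 of 32 reached it. As many lists as in the real split were found in 3 of 32 splits for IL1beta (18, highest other 19), 2 of 32 for IFNgamma (17, highest other 17), 18 of 32 for TGFbeta1 (7, highest other 12) and 2 of 32 for TNFalpha against IL1beta (18, highest other 18). Chance cannot be excluded for these 4 counts. These splits do not show it either, since some of them keep part of the real difference between the groups. In 1 direction, another split still reached 2085 genes for IL1beta, 1633 for IFNgamma and 856 for TGFbeta1. The median over the other splits that part every pair was 10 lists for TNFalpha, 13 for IL1beta and 12 for IFNgamma. It was 7 for TGFbeta1 and 12 for TNFalpha against IL1beta. Among the 28 splits that do not part the pairs, 24 had as many lists as the real one for TGFbeta1 (highest 19), 6 for IFNgamma (highest 19) and 1 for IL1beta (highest 18), and the cause was not tested. With an estimated correlation these reached at most 2 for TGFbeta1, 0 for IFNgamma and 1 for IL1beta. With an estimated correlation 1 of 32 splits, the real one, reached the count in each comparison: 5 lists for TNFalpha (highest other 4), 7 for IL1beta (highest other 1), 10 for IFNgamma (highest other 0), 3 for TGFbeta1 (highest other 1) and 9 for TNFalpha against IL1beta (highest other 0).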

How the results depend on the processing

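Leaving out the medium library of differentiation 5 and leaving out the IFNgamma library of differentiation 6 were tests chosen after the data were seen, and the others were planned. The counts of genes against medium and between TNFalpha and IL1beta stayed within 1.5 times under other size factors, limma-voom, a filter of 1 CPM and a fit of only the groups compared. Where the text below gives no reason, the cause was not tested.

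With DESeq2, 185 genes were lower with TNFalpha in place of 121. Without a filter on low counts TNFalpha lowered 80 genes and 0 were raised selectively. With the replicate block in edgeR TNFalpha raised 737 and lowered 545 genes, 19 selectively, and with the replicate block in DESeq2 938 and 904, and 60 selectively. The replicate block changed no other count of genes higher, lower or raised selectively over all genes tested by more than 1.5 times. Counts within gene lists could change more. Ribosomal protein genes higher with TNFalpha than with IL1beta went from 4 to 18 with the block in edgeR. With an adjusted p under 0.01, TNFalpha raised 209 genes, lowered 47 and raised 0 selectively.

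Asking for at least a 2-fold change removes smaller changes by construction. TNFalpha then raised 101 and lowered 7 genes, IFNgamma 704 and 531, IL1beta 1080 and 997, and TGFbeta1 335 and 217. Between TNFalpha and IL1beta 793 were higher and 809 lower. The selective counts were 1 for TNFalpha, 492 for IL1beta, 330 for IFNgamma and 180 for TGFbeta1.

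Leaving out 1 differentiation or 1 of the 2 libraries gave 220 (without differentiation 3) to 388 (without the IFNgamma library of differentiation 6) genes higher and 47 to 168 lower with TNFalpha, and 0 to 3 selective genes. CXCL10 with TGFbeta1 ranged from -5.08 without differentiation 2 to 0.29 without differentiation 5, and changed sign also without the medium library of differentiation 5 (0.11). A change of sign was counted where the main fit or the alternative passed the threshold. These 2 were the only such changes among 10525 values of 704 pairs of a named gene and a comparison. Of those values, 400 lost the threshold and 69 gained it, in 111 pairs in all.

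Of 185 list tests 77 passed with the preset correlation, 34 with an estimated correlation, 87 with the replicate block, 36 with the replicate block and an estimated correlation and 111 with fry. With an estimated correlation, the replicate block lost 6 lists and gained 8. Lost were interferon-stimulated genes and feedback inhibitors (adjusted p = 0.0575 each) and T-cell genes (0.059) with IL1beta, alternative activation with TGFbeta1 (0.0563), and interferon-stimulated genes (0.0502) and feedback inhibitors (0.0635) in TNFalpha against IL1beta. Gained were matrix (0.00659), cholesterol (0.00803) and LXR genes (0.024) with TNFalpha, matrix and cholesterol (0.0245 each), metallothionein (0.0205) and drug target genes (0.0483) with IL1beta, and cell cycle genes with TGFbeta1 (0.0205). Fry asks another question. The count for it uses its p for members that move on balance one way, without a comparison with other genes. The share of variance between cytokines was 49.5% and that between differentiations 15.9%, and 67.4% and 11.8% over called genes, which were chosen for differing between groups. Leaving out 1 differentiation gave 49.3 to 53.4% and 12.3 to 16%.

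With split controls, which also leave 3 libraries in place of 6 on each side, the correlation of responses was lower. In r the 2 causes were not separated. The covariance went from 0.1477 to 0.131 for TNFalpha and IL1beta, and from 0.2208 to 0.2053 for IL1beta and IFNgamma. In the simulated groups the shared medium libraries alone gave covariances of 0.0155 and 0.0154. The value of r was 0.47 for TNFalpha and IL1beta, 0.15 for TNFalpha and IFNgamma, -0.03 for TNFalpha and TGFbeta1, 0.35 for IL1beta and IFNgamma, 0 for IL1beta and TGFbeta1 and -0.05 for IFNgamma and TGFbeta1. Over called genes it was 0.73 for TNFalpha and IL1beta and 0.03 for TNFalpha and TGFbeta1.

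On simulated data, drawn without differences between differentiations, 76% of genes changed 1.5-fold were found, and 94% of those changed 2-fold. Whether depth or the spread between samples sets this was not tested.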

Other observations

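The lists and genes below were examined as planned, except that SMAD3, CDH1, CXCR3, TAL1 and GP1BA were singled out after their values were seen.

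Of 27 cytokine receptor genes, 12 rose and 10 fell with IL1beta (adjusted p = 0.482), 10 and 8 with IFNgamma (adjusted p = 0.723), 8 and 7 with TGFbeta1 (adjusted p = 0.82) and 3 and 1 with TNFalpha (adjusted p = 0.285), or 1 and 1 without the medium library of differentiation 5. Over the list alone these were 13 and 11, 11 and 8, 8 and 8, and 6 and 2. IL1RAP, the second chain of the IL1 receptor, fell 2.01-fold with IL1beta (-1.01 ± 0.08) and TNFRSF1B 1.31-fold (-0.39 ± 0.06). Of 14 chemotactic receptor genes, 3 rose and 6 fell with IL1beta (adjusted p = 0.496), and CXCR3 fell 9.29-fold with IFNgamma (-3.22 ± 0.37). SMAD3, lowered by TGFbeta1, rose 4.13-fold with IFNgamma (2.05 ± 0.29).

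Of 22 glycolysis and hypoxia genes, 7 rose and 5 fell with IL1beta (adjusted p = 0.229) and 8 and 4 with IFNgamma (adjusted p = 0.331), or 4 and 3 without the medium library of differentiation 5. Of 19 oxidative burst and iron genes, 10 rose and 6 fell with IL1beta (adjusted p = 0.106). Of 20 immediate early genes, 9 rose and 2 fell with IFNgamma (adjusted p = 0.18, and 0.0463 with the replicate block, where adjusted p = 0.459 with an estimated correlation), and 5 rose and 7 fell with IL1beta (adjusted p = 0.873).

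Of 21 macrophage identity genes, 6 rose and 7 fell with IL1beta (adjusted p = 0.543), 8 rose and 4 fell with IFNgamma (adjusted p = 0.252), 3 rose and 4 fell with TGFbeta1 (adjusted p = 0.846) and 1 rose and 1 fell with TNFalpha (adjusted p = 0.664). FCGR1A, a high-affinity Fc receptor, rose 3.49-fold with IFNgamma.

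Markers of other cell types were few among the genes tested. Of 6 pluripotent cell markers, 2 rose and 3 fell with IL1beta (adjusted p = 0.967), or 1 and 2 without the medium library of differentiation 5, with POU5F1 4.36-fold higher (2.12 ± 0.23), and 2 rose with TGFbeta1 (adjusted p = 0.0802), DNMT3B 3.71-fold. The median of the list with IL1beta was -0.18 and the mean 0.30. Of 6 endothelial markers, 2 fell with IL1beta (adjusted p = 0.0843, and 0.026 with the replicate block, where adjusted p = 0.0635 with an estimated correlation), CDH5 by 1.95 ± 0.30 on the log2 scale. Of 6 epithelial markers, 1 rose and 3 fell with IL1beta (adjusted p = 0.707), and 1 rose with TGFbeta1 (adjusted p = 0.148, and 0.0405 with the replicate block, where adjusted p = 0.0869 with an estimated correlation), CDH1, the gene of E-cadherin, by 5.33 ± 0.72, and 6.55 without differentiation 4. Of 9 stromal markers, 2 rose with TGFbeta1 (adjusted p = 0.259), 2 with IFNgamma (adjusted p = 0.72) and 1 rose and 1 fell with IL1beta (adjusted p = 0.799). None of 13 granulocyte and mast cell markers passed with TNFalpha (adjusted p = 0.0195, and 0.571 with an estimated correlation), while 5 rose with the replicate block, and 2 rose and 1 fell with IL1beta (adjusted p = 0.69). Of 5 erythroid and megakaryocyte markers, 1 rose with IL1beta (adjusted p = 0.69), GP1BA, 74.8-fold (6.22 ± 0.48). TAL1, a transcription factor of blood progenitors, fell 14.8-fold with IL1beta (-3.88 ± 0.26). Only 2 lymphocyte markers were tested, and 1 of them rose with IL1beta and 1 with TGFbeta1. Dendritic cell markers rose and fell with IL1beta (5 and 3 of 9, adjusted p = 0.224).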
